A study of Medicago sativa with 15 samples.

How the data were processed

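RNA was sequenced from roots of seedlings of alfalfa (Medicago sativa), a perennial forage legume with a tetraploid, outcrossing genome. The 15 libraries fall into 5 groups of 3: roots under normal conditions, and roots kept for 4, 8, 12 or 24 h under alkaline stress from NaHCO3 at 50 mmol/L. Groups and replicate numbers were taken from the sample titles. The treatment field of the control libraries also reads alkaline stress, so the title decided the group. Total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit, per the labels' protocols. Nothing in the labels says that replicates came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical. The control has no time of its own, so the duration of stress cannot be separated from the time of sampling.

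A pair of tables was deposited by the authors. The first holds raw read counts per gene for 164632 gene IDs, as whole numbers that sum to between 6863315 and 15180708 per library. The second holds FPKM (fragments scaled by gene length and library total) for the same IDs, also deposited by the authors. In each of the 108456 genes with a count, the deposited FPKM and count gave 1 gene length in every library, within 0.01 nt, so the FPKM values are the counts divided by the library total and a fixed length. Of these lengths 95.96% were multiples of 3, so they are called coding lengths here, and their median was 1083 nt. The aligner, the counting tool, the strand setting, the treatment of reads that match several gene copies and the genome build are not given in the sources used here. Since alleles of a tetraploid and paralogs can share reads, the split of reads among near-identical copies is uncertain for every gene.

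The files pair no gene ID with a name, and 0 of the 164632 IDs were found in the reference table of alfalfa genes from the Bolivia_mono assembly. Gene names, coordinates and prepared gene lists could therefore not be used, and the tests of gene lists were not run. Genes are reported by ID, and groups of genes by direction and time. The rule for the IDs took the 2 genes with the highest and the 2 with the lowest mean log2 fold change over the 4 times, among genes called at all 4 times in one direction with a mean CPM (the count divided by the library total and scaled alike in all libraries) of at least 5. Genes chosen in this way pass at each time by construction.

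Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, libraries were scaled by TMM, and a quasi-likelihood model with 5 groups was fitted to all 15 libraries (glmQLFit, glmQLFTest, two-sided). P-values were adjusted by the Benjamini-Hochberg method over the 68605 genes tested, with a threshold of 0.05 and no limit on fold. Each time was compared with control, 8 h with 4 h, 12 h with 8 h, 24 h with 12 h and 24 h with 4 h, and the 4 times together with control. The standard error of a log2 fold change was taken as its size divided by the square root of F. Beside a group without counts, a fold is a lower bound against 3 counts over the group's 3 libraries. Means ± SD over 3 libraries count the intermediate library defined in the next paragraph. The bounds with each library left out were added after seeing the data. Leaving out a stressed library that is not intermediate keeps the intermediate one, so such a bound is no independent check. Ratios of pooled counts carry exact 95% Poisson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

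Each library was compared with the other 2 of its group before any averaging, over genes with at least 300 counts in the 3 libraries together. The share of genes at which it lay between the others was taken, and a non-negative weighted sum of the others was fitted to it. On simulated data, with each gene drawn independently, this measure gave 33.4% of genes for independent libraries and 90.5% for a library drawn from a pool of the other 2. One library in each stressed group stood out (4 h replicate 2, 8 h replicate 3, 12 h replicate 1 and 24 h replicate 1), and these 4 are called intermediate libraries. Every comparison was repeated on the 11 other libraries (71665 genes tested), and a test of the 8 remaining stressed libraries against the 3 controls was added. These were chosen after seeing the data.

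Alternatives were DESeq2 size factors or upper-quartile scaling, no filter or a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), limma on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM of at least 1 in 3 libraries or no filter, only the 2 groups compared, the replicate number as a block, a threshold of 0.01, a limit of 2-fold, and each library left out in turn. The groups, the comparisons, the tests, the rule for the IDs and these alternatives were fixed before the data were examined. Whether replicate numbers pair the libraries was checked by the correlation of same-numbered deviations from group means. Counts of detected genes were compared after thinning every library to 6863315 counts. The p-values of the exact tests were adjusted over the 4 times, and those of the 2 tests of library similarity over both, by the Benjamini-Hochberg method. In the edgeR self-test, counts were simulated from the real means and library sizes of the 15 libraries and the dispersions of the 11. In it 200 genes were changed at 4 h, all drawn from genes with a mean CPM of at least 5. The shares called hold for such genes only. With 15 independent libraries 18.0% of the genes changed 16-fold were called and 1.0% of those changed 4-fold, with 1 unchanged gene called among 64838 tested. With 11 libraries the shares were 2.0% and 0.0%, with 0 unchanged genes called among 65856 tested.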

Results

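The transcriptome of alfalfa roots was measured under normal conditions and after 4, 8, 12 and 24 h of alkaline stress, with 3 libraries per group. NaHCO3 at 50 mmol/L raises the pH, the bicarbonate and the sodium around the root. No group received sodium without bicarbonate, so these parts cannot be separated. The libraries held between 6863315 and 15180708 counts. At the low end, 4 libraries had at most 7621064 counts, and the other 11 had 11266060 or more. Of the 164632 genes in the tables, 108456 had a count in at least 1 library and 56176 had none. Between 64162 and 80581 genes had a count in a single library. The 10 most abundant genes took 2.74% to 3.20% of the counts in the control libraries and 3.67% to 6.49% in the stressed libraries.

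Before the groups were compared, each library was set against the others. The 3 control libraries resembled one another, with a Pearson correlation of log2(CPM + 1) between 0.799 and 0.876 across 27967 genes with a mean CPM of at least 5. In each stressed group, 1 library lay between the other 2 at most genes. These were 4 h replicate 2 (79.0% of genes), 8 h replicate 3 (75.6%), 12 h replicate 1 (79.3%) and 24 h replicate 1 (72.1%). In the control libraries the share was 23.1% to 38.8%, and in the other stressed libraries 9.8% to 14.5%. The 4 intermediate libraries were also the 4 shallowest, with 0.518 to 0.540 of the mean total of the other 2. A weighted sum of the other 2 libraries fitted each of them to within 2.85 to 3.13 times the counting noise (median squared residual), against 17.3 to 66.1 for the other libraries. The weights were 0.248 to 0.289, and the lower-numbered of the other 2 libraries gave 48.7% to 52.4% of the fitted counts.

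Without the intermediate libraries, the 2 remaining libraries of a stressed group were less alike than the controls. Their correlation was 0.559 at 4 h, 0.651 at 8 h, 0.528 at 12 h and 0.719 at 24 h. Pairs from different times had a median correlation of 0.565 (range 0.465 to 0.679, 24 pairs), and pairs of a stressed and a control library had a median of 0.491 (0.416 to 0.563, 24 pairs). Over the 11 libraries, members of a group were more alike than members of different groups (difference in mean correlation 0.174, one-sided permutation test, p = 0.00074, adjusted over 2 tests 0.00148). Among the 8 stressed libraries alone, grouping by time was not distinguishable from other pairings (difference 0.0412, exact one-sided test over all 105 pairings, p = 0.114, adjusted 0.114). For this reason each comparison is given for all 15 libraries and for the 11 libraries without the intermediate ones.

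**Figure D1:**
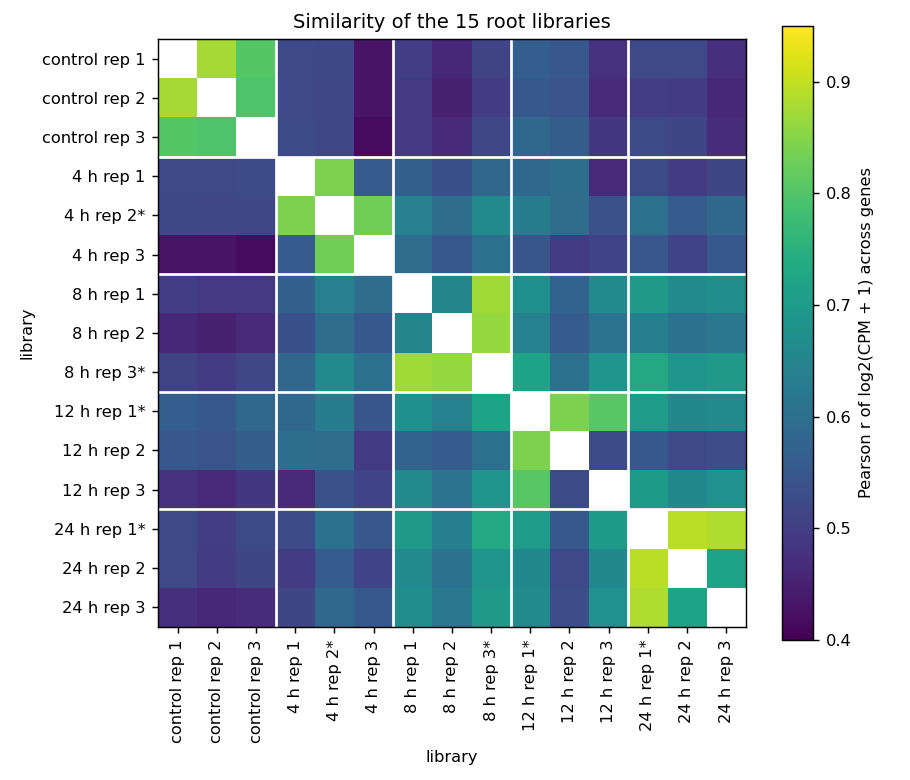
Pearson correlation of log2(CPM + 1) across 27967 genes for every pair of the 15 libraries (both axes, grouped by time; an asterisk marks the 4 intermediate libraries; the diagonal is blank). The control pairs reach 0.799 to 0.876, while the 2 other libraries of a stressed time reach 0.528 to 0.719.

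The comparison of 4 h with control asks which genes differ at the earliest time sampled. With all 15 libraries, 13005 of 68605 genes changed at 4 h by edgeR's adjusted p, 8591 lower and 4414 higher. This was the highest number of the 4 times in that fit, but not when only the 2 groups compared were fitted (7391 at 4 h, 9144 at 8 h, 4301 at 12 h and 9477 at 24 h), nor with the 11 libraries in edgeR. MS.gene72495 (coding length 594 nt) had no count in the controls and 13.1 ± 12.1 CPM at 4 h (SD, n = 3), which is at least 171-fold higher. Its libraries had 0.153, 15.1 and 24.1 CPM, and without 4 h replicate 3 the bound was 99-fold. That bound rests on 4 h replicate 2, the intermediate library, since 4 h replicate 1 had only 2 counts. MS.gene77725 (also 594 nt) had no count in the controls and 8.44 ± 5.43 CPM at 4 h, at least 110-fold higher. Their edgeR adjusted p was 0.0195 and 0.0105. MS.gene040116 (387 nt) had 54.8 ± 40.2 CPM in the controls and no count in any 4 h library, at least 636-fold lower (edgeR adjusted p = 0.00229). Its control replicates 1, 2 and 3 had 90.2, 63.1 and 11.1 CPM, and without each in turn the bound was 430-fold, 587-fold and 889-fold. The controls of MS.gene044933 had 97.4, 63.1 and 18.1 CPM. The bounds of both genes at later times use the same controls. MS.gene044933 (414 nt) had 59.5 ± 39.8 CPM in the controls and 7 counts at 4 h against 2445, a level 311-fold lower (95% Poisson interval 151 to 775, edgeR adjusted p = 0.0021). All 7 counts came from 4 h replicate 1 and the other 2 libraries had none, so the ratio rests on that library; without it the level was at least 431-fold lower. The 4 genes were chosen among those called at all 4 times, so that they pass at each time follows from the choice. Whether some of the 4 IDs are copies of one gene was not tested. The 2 lower IDs both had 852 counts in control replicate 2. The 2 higher IDs share a length, but had 0.153 and 13.4 CPM in 4 h replicate 1. Leaving out a library of a group without counts moved a bound by up to 1.74 times, through the smaller total alone. On the 11 libraries edgeR called 32 genes, 15 higher and 17 lower, and all 32 were among the 13005 and in the same direction, in fits that share libraries. None of the 4 named genes was among them. There limma-voom called 1773 genes and DESeq2 7325. In unchanged groups simulated with 11 libraries the mean calls at 4 h were 0.125 for edgeR (8 simulations), 0 for limma-voom and 118 for DESeq2 (2 simulations each). The simulation gave every group 1 spread, so these values are no bound on false calls here. In the 15-library fit the count was 8119 without control replicate 1, 8361 without control replicate 2, 5137 without 4 h replicate 2 and 8651 without 4 h replicate 3. MS.gene72495 missed the threshold at 4 h when any 1 control was left out (edgeR adjusted p 0.0518 to 0.0558).

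After 8 h, 8506 genes differed from control with all 15 libraries, 5000 lower and 3506 higher. MS.gene77725 stood at 208 ± 198 CPM (SD, n = 3), at least 2710-fold above the controls. Its libraries had 406, 10.5 and 209 CPM, so the SD was nearly as large as the mean, and without 8 h replicate 1 the bound was 1430-fold. MS.gene72495 stood at 112 ± 102 CPM, at least 1460-fold higher, or 817-fold without 8 h replicate 1. The bounds without 8 h replicate 1 keep 8 h replicate 3, the intermediate library. In 8 h replicate 2 alone MS.gene77725 had 10.5 CPM and MS.gene72495 had 7.11 CPM. MS.gene040116 again had no count in any library, at least 665-fold lower, and MS.gene044933 had 1 count, in 8 h replicate 1, against 2445 in the controls, a level 2280-fold lower (95% Poisson interval 409 to 90100), or at least 452-fold without that library. Their edgeR adjusted p ran from 0.00182 to 0.00863. In the fit of 11 libraries 11 genes passed, 9 higher and 2 lower, all in the same direction as with 15; limma-voom called 836 and DESeq2 4745. None of the 4 named genes passed in edgeR there. Leaving out 1 library lowered the 15-library count to 4616, 4570 and 5629 without control replicates 1, 2 and 3, and to 5182, 4706 and 2845 without 8 h replicates 1, 2 and 3. The excess of lower genes was lost without 8 h replicate 3 (1462 higher, 1383 lower).

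At 12 h the number of changed genes was lowest, at 4999 with all 15 libraries, 2994 lower and 2005 higher. MS.gene72495 had 40.7 ± 41.1 CPM and MS.gene77725 41.8 ± 40.3 CPM (SD, n = 3), at least 530-fold and 544-fold above the controls. Replicate 3 carried much of this, since MS.gene72495 had 39.6, 0.227 and 82.4 CPM and MS.gene77725 40.7, 2.12 and 82.6 CPM in replicates 1, 2 and 3. Without 12 h replicate 3 the means were 19.9 and 21.4 CPM and the bounds 259-fold and 278-fold. These values keep 12 h replicate 1, the intermediate library, which resembles a pool of replicates 2 and 3. Replicate 2 alone, with 0.227 and 2.12 CPM, lay far below these means, so the bounds are no independent check. Neither MS.gene040116 nor MS.gene044933 had a count in any 12 h library, at least 589-fold and 640-fold below the controls. The 4 genes had edgeR adjusted p between 0.00201 and 0.0197. With the 11 libraries edgeR called 0 genes, with 7811 at an unadjusted p below 0.05; limma-voom called 226 and DESeq2 2837. MS.gene72495 missed the threshold at 12 h in edgeR when any 1 control or 12 h replicate 1 was left out. The 15-library count fell to 2098, 2086 and 3181 without control replicates 1, 2 and 3, and to 1171 and 2772 without 12 h replicates 1 and 3. The excess of lower genes was not stable, with 600 higher and 571 lower without 12 h replicate 1, 1859 and 1693 without 12 h replicate 2, and 2940 and 2889 with 11 libraries that kept the intermediate ones. DESeq2 on the 15 libraries gave 10364 genes and limma on log2(FPKM + 1) gave 8187.

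By 24 h, 7870 genes differed from control with all 15 libraries, 4709 lower and 3161 higher. MS.gene72495 stood at 145 ± 51.5 CPM (SD, n = 3), at least 1890-fold above the controls, and MS.gene77725 at 72 ± 56.1 CPM, at least 937-fold higher, or 571-fold without 24 h replicate 3. The 571-fold bound keeps 24 h replicate 1, the intermediate library, and 24 h replicate 2 alone had 16 CPM. No 24 h library had a count of MS.gene040116 or MS.gene044933, at least 629-fold and 683-fold below the controls. Adjusted p in edgeR ran from 0.0014 to 0.00803 for these 4 genes. Among the 11 libraries 101 genes passed, the most of the 4 times, 65 higher and 36 lower, so that higher genes prevailed, and all 101 were called in the same direction with 15. The 4 named genes were again outside. On those libraries limma-voom called 1174 genes and DESeq2 4477. The 15-library count was 4325 and 4084 without control replicates 1 and 2, and 2580, 4479 and 4106 without 24 h replicates 1, 2 and 3.

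**Figure D2:**
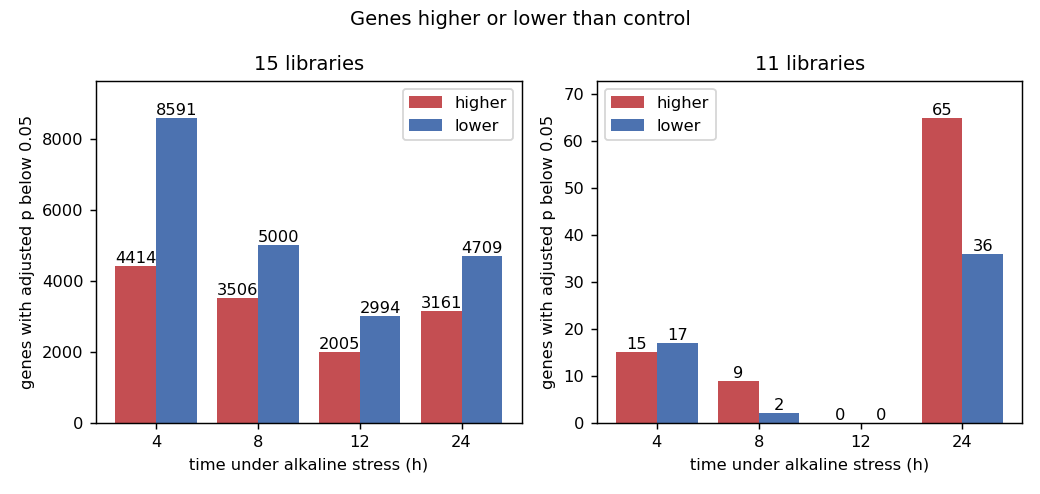
Number of genes with an edgeR adjusted p below 0.05 against control (y axis; the scales of the panels differ) at each time under stress (x axis, h), split into higher and lower, for 15 libraries (left) and for 11 libraries without the intermediate ones (right). Genes lower at 4 h are the largest class on the left (8591), and at most 65 genes stand in any class on the right.

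**Figure D3:**
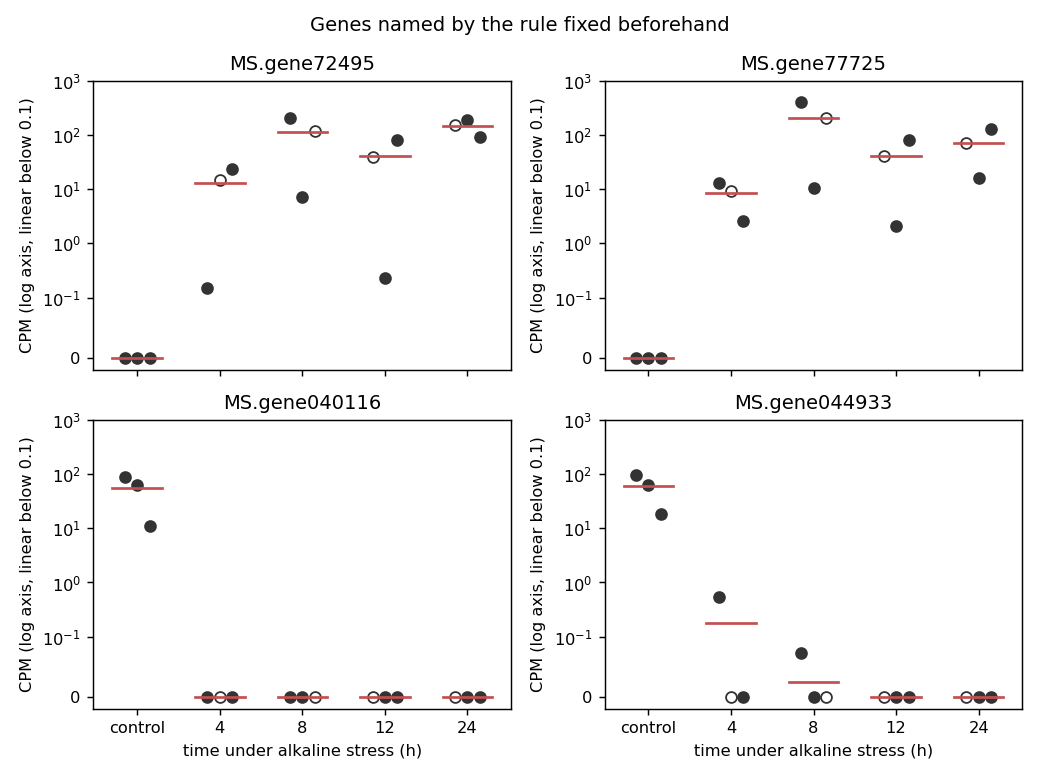
CPM (y axis, log scale that is linear below 0.1) of the 4 named genes in each library by time under stress (x axis, h); open circles are the intermediate libraries and red lines are means over 3 libraries. MS.gene72495 and MS.gene77725 are at 0 in the 3 controls, and MS.gene040116 is at 0 in all 12 stressed libraries.

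Genes that differed from control throughout the time course were then counted. With 15 libraries, 1540 genes changed at all 4 times in one direction, 915 lower and 625 higher. Independent lists would share 1.88 lower and 0.304 higher genes. Unchanged groups simulated with shared controls had a mean of 0 such genes with independent libraries and 2.75 with intermediate libraries drawn from the other 2. They had few calls to share, a mean of 0.125 and 220 at 4 h against 13005 in the data. What shared controls add to lists as long as the real ones was therefore not measured. With the 11 libraries, edgeR called 0 genes at all 4 times, since it called none at 12 h. The 1540 fell to 571 without 12 h replicate 1, 679 and 698 without control replicates 2 and 1, and 740, 792 and 840 without 24 h replicate 1, 8 h replicate 3 and 4 h replicate 2.

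The 4 h and 24 h responses were compared across genes, which are not independent replicates. Their log2 fold changes had a correlation of 0.426 over 68605 genes, and of 0.441 over 71665 genes with the 11 libraries. Sharing the 3 control libraries gives a correlation without any effect, 0.496 in simulated unchanged groups with 15 independent libraries, 0.368 with 15 of which 4 were drawn from the other 2 of their group, and 0.377 with 11. The covariance was 2.62 against a simulated 0.837 (independent) or 0.822 (4 drawn from the others) with 15 libraries, and 2.99 against 0.873 with 11, so it exceeded the part from shared controls by 1.78, 1.80 and 2.12. The 4 h and 24 h calls shared 1453 higher and 2098 lower genes, where independent lists would share 203 and 590. Simulated unchanged groups shared a mean of 0.125 genes, or 17.6 with intermediate libraries. With a mean of only 0.125 or 220 calls at 4 h they had few to share, so these values are no reference for the real lists. Part of the excess may come from the shared controls, which were not divided between the comparisons. The simulation measured that part for the covariance, with 1 spread for every group, but not for the shared calls.

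Stressed roots were compared between times. With 15 libraries 24 h and 4 h differed at 10555 genes, 6453 higher and 4102 lower at 24 h. From 4 h to 8 h 4629 genes rose and 2576 fell, 7205 in all. The later steps were smaller, with 1251 genes from 8 h to 12 h (667 higher, 584 lower) and 1923 from 12 h to 24 h (798 higher, 1125 lower). Between 4 h and 24 h the fitted log2 difference was 3.50 for MS.gene72495, 3.12 for MS.gene77725 and -4.27 for MS.gene044933 (7 counts at 4 h and 0 at 24 h, so the fitted value depends on the prior count), and none passed the test (edgeR adjusted p 0.141, 0.104 and 0.152). MS.gene040116 had no count at either time. With the 11 libraries edgeR called 0 genes in each of these 4 comparisons, with 9267, 7636, 4030 and 4526 genes at an unadjusted p below 0.05. Without any change a share of 0.05 of the 71665 genes tested would have such a p, which is not far below 4030 and 4526. There limma-voom also called 0 genes in each, while DESeq2 called 3755, 2386, 459 and 641. With 11 libraries that kept the intermediate ones, edgeR called 5899, 4554, 436 and 380. Without 4 h replicate 2 the 15-library count for 24 h against 4 h was 3391, and it was 6991, 3651, 5754 and 6937 without 4 h replicate 1 and 24 h replicates 1, 2 and 3. For 8 h against 4 h it was 4339 and 1594 without 4 h replicates 1 and 2, and 4316 and 2081 without 8 h replicates 2 and 3. For 12 h against 8 h it was 454, 349 and 53 without 8 h replicates 1, 2 and 3, and 71 and 450 without 12 h replicates 1 and 2. For 24 h against 12 h it was 221 and 579 without 12 h replicates 1 and 2, and 119, 392 and 519 without 24 h replicates 1, 2 and 3. Without any 1 of the 8 h libraries lower genes prevailed from 8 h to 12 h (294, 225 and 31 lower against 160, 124 and 22 higher). From 12 h to 24 h higher genes prevailed without any 1 of the 24 h libraries (73, 222 and 295 higher against 46, 170 and 224 lower).

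Some change against control was called at 22376 genes when the 4 times were tested together with 15 libraries. Unchanged groups simulated with 4 libraries drawn from the other 2 gave a mean of 4760 calls in this test. With 1 spread for every group, that value is no bound on false calls. With the 11 libraries this test called 392 genes, of which 390 were among the 22376, and limma-voom called 652 and DESeq2 8646. MS.gene040116 and MS.gene044933 were among the 392 (edgeR adjusted p 0.0173 for both), and MS.gene72495 and MS.gene77725 were not (0.184 and 0.0915). Without 4 h replicate 2 the 15-library count was 14269.

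A stressed root, whatever the time, was compared with a control root by pooling the 8 stressed libraries that are not intermediate against the 3 controls, a test added after seeing the data. It called 1416 of 65129 genes, 1091 lower and 325 higher in stressed roots, and 1146 of these were among the 1540 genes changed at all 4 times, which were called on a set that includes the same libraries. In the 11 libraries 29 of the higher genes had no count in the controls, and 56 of the lower genes had none in the 8 stressed libraries. The 4 named genes, chosen as extreme on libraries that include these 11, had log2 fold changes of 13.06 ± 3.11 (SE) for MS.gene72495, 13.17 ± 2.86 for MS.gene77725, -12.46 ± 1.02 for MS.gene040116 and -9.40 ± 1.09 for MS.gene044933 (edgeR adjusted p 0.0472, 0.0316, 0.00166 and 0.000821). Where a group has no count these fitted values depend on the prior count. Without any threshold on p, all 8 stressed libraries lay below all 3 controls at 2132 of 27967 genes (7.62%) and above them at 1166 (4.17%). Averaged over all splits of exchangeable libraries the share is 0.606% each way. A single split can lie far from that average where genes vary together. No other split was counted, so no conclusion on chance is drawn from these shares. The excess of lower genes depended on the test: DESeq2 called 2865 higher and 2600 lower genes, and limma-voom 397 higher and 3340 lower. Leaving out a control lowered the count of 1416 to 287, 317 and 572 for replicates 1, 2 and 3. The higher genes fell from 325 to 13, 17 and 40 in these fits, and the lower genes from 1091 to 274, 300 and 532.

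The number of genes detected was compared at 1 depth, after thinning to 6863315 counts. Control libraries had 74442 ± 2530 genes with a count (SD, n = 3) and 4 h libraries had 63770 ± 4353, a difference of -10672 genes. Each 4 h library was below each control (exact two-sided permutation test, p = 0.1, adjusted over the 4 times 0.4, where 3 against 3 allows no p under 0.1). The 8 h, 12 h and 24 h libraries had 71760 ± 3268, 74403 ± 3832 and 71146 ± 3872 genes (exact p of 0.3, 1 and 0.2, adjusted 0.4, 1 and 0.4). Without the intermediate libraries, the 2 libraries had 60951 and 61575 genes at 4 h, 69679 and 70074 at 8 h, and 67477 and 70767 at 24 h, all below each control (71618 to 76500). The exact p was 0.2 at each of these 3 times (adjusted 0.267), the smallest that 2 against 3 allows. At 12 h the libraries had 71017 and 73630 genes (exact p = 0.4, adjusted 0.4). The intermediate library had the most detected genes of its group at every time, between 68784 and 78563.

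**Figure D4:**
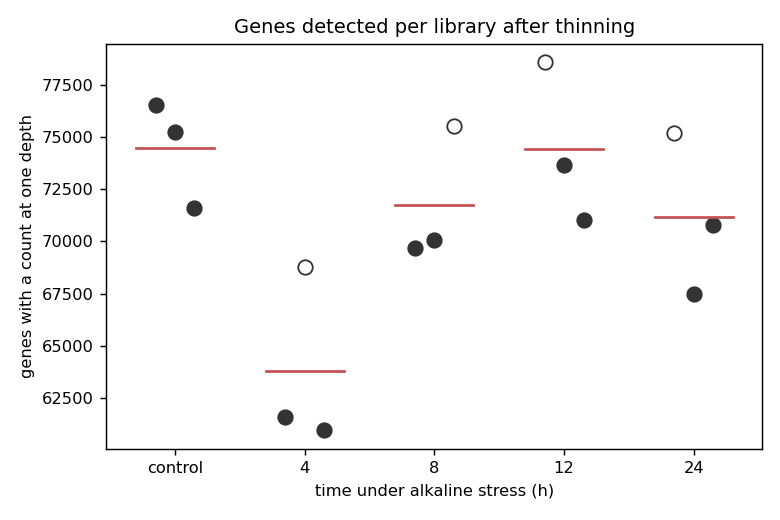
Genes with at least 1 count per library after thinning to 6863315 counts (y axis, not starting at 0) by time under stress (x axis, h); open circles are the intermediate libraries and red lines are means over 3 libraries. The 4 h libraries lie between 60951 and 68784, below the controls at 71618 to 76500.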

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

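The fits on 11 libraries, the one that left out other libraries included, and the comparison of 8 stressed libraries with 3 controls were chosen after seeing the data, while the bounds for the simulations, for the fit without other libraries and for the splits were set down before their results. Effects against control that differed between times by a test of the difference were found at 10555 genes for 24 h against 4 h, 7205 for 8 h against 4 h, 1923 for 24 h against 12 h and 1251 for 12 h against 8 h. These are the 15-library counts of edgeR, and each is 0 in edgeR and limma-voom with the 11 libraries, where 9267, 7636, 4526 and 4030 genes had an unadjusted edgeR p below 0.05 and DESeq2 called 3755, 2386, 641 and 459. A share of 0.05 of the 71665 genes tested would have such a p without any change, not far below 4526 and 4030. No group has the 4 samples that the rule chosen here for an outlying library asks for, so no such test was run.

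Whether fewer libraries alone account for the fall from 13005 changed genes at 4 h to 32 without the intermediate libraries was not settled. Leaving out 1 other library per stressed group gave 13669 genes. That fit keeps each intermediate library beside a library it resembles, so its own spread may be too small. In the self-test with independent libraries, going from 15 to 11 libraries lowered the share of 16-fold changes called from 18.0% to 2.0%. A candidate explanation is that libraries that are not independent make the spread within a group too small. Unchanged groups simulated with 4 libraries drawn from the other 2 gave a mean of 220 edgeR calls at 4 h, against 0.125 with independent libraries, and 4760 calls when the 4 times were tested together. In 2 such simulations DESeq2 gave a mean of 3680 calls at 4 h and limma-voom 43.5, against 54.5 and 0 with independent libraries. The 220 are far fewer than 13005. The self-test with 11 libraries changed 100 genes 16-fold and 100 genes 4-fold among 65856 tested. The share called after adjustment depends on how many genes change. In the real data, 12973 of 71665 genes had an unadjusted edgeR p below 0.05 at 4 h with 11 libraries. The self-test therefore does not give the share of true changes that edgeR on 11 libraries detects here. Some of the lost genes may be real differences, but how many was not tested. The simulation of unchanged groups gave every group 1 spread, while the stressed libraries varied more than the controls. Its count of 220 is therefore no bound.

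For each comparison of 3 libraries with 3, the 10 possible splits cannot give a share under 0.05. The real split gave 13005, 8506, 4999 and 7870 genes for 4, 8, 12 and 24 h against control, and the highest other split gave 0, 0, 2 and 0. Between times, the real 7205 (8 h against 4 h), 1251 (12 h against 8 h), 1923 (24 h against 12 h) and 10555 (24 h against 4 h) stood beside 1, 0, 0 and 0. In each case 1 split of 10, the real one, gave as many. For the 4 times together, 1 of 25 splits of the 15 libraries, the real one, gave as many as 22376 (highest other 79). For genes changed at all 4 times the real split gave 1540 and the highest other 0, again 1 of 25. A split that parts an intermediate library from the 2 it resembles is not equivalent to the real one, so these shares are too small if the libraries are not independent. The number of splits drawn was lowered to 25 to save time, after a first run with more had given the same highest counts of the other splits. For the 8 stressed against the 3 control libraries, which include no intermediate library, the real split gave 1416 and the highest of 24 others gave 1 (1 of 25). Only some of the other splits were drawn, and the comparison was itself chosen after seeing the data. The controls were also closer to each other than stressed libraries, and replicates may be technical. Chance is therefore not excluded for this comparison.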

How the results depend on the processing

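The 4 named genes kept their direction at every time under the alternatives run for them. This follows from their choice as extreme genes, with no or almost no counts in the controls or in the stressed libraries. The correlation of fold changes stayed positive, but shared controls alone gave 0.368 to 0.496 in simulated unchanged groups. Neither result is therefore a check on the processing. Whether more genes were higher or lower turned in several counts. In the pooled comparison it went from 325 higher and 1091 lower to 2865 and 2600 with DESeq2. At 8 h (3506 and 5000) it went to 1462 and 1383 without 8 h replicate 3 and to 9 and 2 with the 11 libraries, and at 24 h (3161 and 4709) to 65 and 36 with the 11 libraries. At 12 h (2005 and 2994) it went to 600 and 571 without 12 h replicate 1, 1859 and 1693 without 12 h replicate 2, and 2940 and 2889 with other libraries left out. For 12 h against 8 h (667 and 584) it went to 160 and 294, 124 and 225, and 22 and 31 without 8 h replicates 1, 2 and 3, and to 646 and 647 with upper-quartile scaling. For 24 h against 12 h (798 and 1125) it went to 73 and 46, 222 and 170, and 295 and 224 without 24 h replicates 1, 2 and 3. It did not turn under the alternatives run at 4 h and at all 4 times, or for 8 h and 24 h against 4 h, where edgeR called any gene. The alternatives on 11 libraries, and those of the pooled comparison, were chosen after seeing the data. In the order 4, 8, 12 and 24 h against control, then 8 h against 4 h, 12 h against 8 h, 24 h against 12 h and 24 h against 4 h, then the 4 times together, the counts of 15 libraries were 13005, 8506, 4999, 7870, 7205, 1251, 1923, 10555 and 22376. An adjusted p below 0.01 gave 3917, 2436, 1111, 2251, 1279, 64, 124, 2446 and 7757. Without the intermediate libraries they were 32, 11, 0, 101, 0, 0, 0, 0 and 392, with DESeq2 on those libraries 7325, 4745, 2837, 4477, 2386, 459, 641, 3755 and 8646, and with limma-voom 1773, 836, 226, 1174, 0, 0, 0, 0 and 652. With other libraries left out in their place, the comparisons with control stayed within 1.5 times, and the 4 between times gave 4554, 436, 380 and 5899. DESeq2 on 15 libraries gave 14312, 10364 and 13592 genes at 8, 12 and 24 h, 13667, 6663, 7566 and 16915 between times, 34029 for the 4 times together and 2754 genes changed at all 4 times, against 1540. Fitting only the 2 groups gave 7391 at 4 h, 3089 for 8 h against 4 h, 1 for 12 h against 8 h and 6255 for 24 h against 4 h; with 9144 genes at 8 h and 9477 at 24 h, 4 h was then not the time with most changed genes. No filter gave 2952 for 12 h against 8 h and 3655 for 24 h against 12 h. In the same 2 comparisons limma on log2(FPKM + 1) gave 2975 and 3983, without a filter 3122 and 4149, and with a pseudocount of 0.1 2559 and 3454; at 12 h against control it gave 8187, and 8699 without a filter. Genes changed at all 4 times numbered 0 without the intermediate libraries. The pooled comparison gave 4288 with 15 libraries, 5465 with DESeq2 and 3737 with limma-voom, against 1416. The causes of these shifts were not tested, beyond the number of libraries, which stayed undecided, and the weighing of the intermediate ones. Leaving out 1 library gave 5137 to 10678, 2845 to 5629, 1171 to 3552 and 2580 to 5413 genes for the comparisons with control. Between times it gave 1594 to 5177, 53 to 1042, 119 to 2124 and 3391 to 7534. The ranges were 14269 to 24123 for the 4 times together, 571 to 1639 at all 4 times, 287 to 1783 for the pooled comparison and 0.404 to 0.459 for the correlation. In each of these except the pooled comparison and the correlation, the lowest count came without an intermediate library. The replicate block gave 4305 (8 h against 4 h), 384 (12 h against 8 h) and 872 (24 h against 12 h) and left the other counts within 1.5 times. Same-numbered deviations correlated above 0.1 in 2 of 30 pairs (-0.047 to 0.156), and 5 of 15 libraries were closest to their own number. No pairing by number was seen. The check cannot exclude pairing, since intermediate libraries lie between the other 2 and their number differs between groups. TMM, DESeq2 size factors and upper-quartile scaling shifted the median log2 fold change by at most 0.098. MS.gene040116 lost its 4 calls with DESeq2, and MS.gene72495 lost 7 of 24 calls when 1 library was left out, 6 of them without a control. Over the alternatives and times, adjusted p reached at most 0.197 for MS.gene72495, 0.125 for MS.gene77725, 0.079 for MS.gene040116 and 0.0785 for MS.gene044933, and was lowest at 1.3e-08, 1.92e-14, 1.14e-07 and 1.26e-07. Each of the 4 genes lost all 4 calls with the 11 libraries, although the fitted log2 fold changes stayed about as large. At 4 h they were 10.41 against 10.29 for MS.gene72495, 9.76 against 9.62 for MS.gene77725, -12.47 against -12.30 for MS.gene040116 and -7.71 against -8.14 for MS.gene044933. With limma on log2(FPKM + 1), MS.gene72495 lost 2 of 4 calls and MS.gene77725 1 of 4. Tests of gene lists were not run, because no ID could be matched to a name. The depth of the 4 intermediate libraries, at most 7621064 counts, limits what they add for low genes.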

Other observations

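The tests of the intermediate libraries and of genotype were chosen after the patterns were seen; the test of depth was set down before its result. With 15 libraries, genes lower at 4 h had a median coding length of 951 nt, against 1377 nt for genes higher at 4 h and 1152 nt for all genes tested. The difference was smaller later, with 987 and 1233 nt at 8 h, 1011 and 1074 nt at 12 h and 1059 and 1125 nt at 24 h. The Spearman correlation of coding length with log2 fold change across genes was 0.16 at 4 h and 0.042 at 24 h. Genes at 5 CPM or more in all 3 controls (19200 genes) were at 0 most often at 4 h, where replicate 3 lacked 825 of them and replicate 1 lacked 506, against 183 to 366 in the other stressed libraries that are not intermediate. Genes are not independent replicates, and no test was made of these values.

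Each stressed time holds 1 shallow library that lies between the other 2. The share of genes at which it does so is at least 72.1%, where independent libraries give about 33.4% in simulation. This argues against an independent library that is intermediate by chance only if genes vary independently, as they did in that simulation. Where many genes vary together, the simulation cannot decide. A plain copy of counted reads is argued against, since at least 1199 genes in each of the 4 have more counts than the other 2 libraries together. RNA or reads of the other 2 (which, the counts do not show), pooled in about equal parts and then sequenced or assigned to gene copies anew, remains a candidate explanation: the residual from a weighted sum was at least 5.53 times smaller than for any other library. It does not account for everything, since a simulated pool lay between at 90.5% of genes with a residual of 0.791 times the counting noise, against 72.1% to 79.3% and 2.85 to 3.13 here.

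Without the intermediate libraries, the control libraries were closer to each other than the 2 libraries of a stressed time; pairs with an intermediate library were about as close as controls (correlation 0.808 to 0.893). Depth is argued against for the pairs without intermediate libraries, since after thinning to 1 depth the SD of the log2 difference was at least 1.30 in those 4 pairs and at most 1.08 in control pairs. Plants of different genotype in each stressed library are possible in an outcrossing species. In each of those 4 pairs at least 632 genes were at 5 CPM or more in one library and at 0 in the other, against at most 311 in control pairs, but a variable response to stress would give such genes as well, so these explanations cannot be told apart without sequence. A different make-up of control and stressed libraries may also enter every comparison with control, and a stress response that varies between plants stays open, as untested.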
